A study of Mus musculus with 12 samples.

How the data were processed

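RNA was measured by poly A RNA sequencing in 12 libraries of mouse hepatocytes. Per the labels' protocols, male wild-type BALB/c mice aged 8 weeks were injected intraperitoneally with 200 µg of an anti-Gr1 antibody or of an isotype antibody in 100 µl of buffer. A second dose followed 2 days later together with removal of 70% of the liver. Hepatocytes were taken on day 1 or day 2 after surgery (post-operative day, POD) by collagenase perfusion of the remnant liver, filtering and low-speed centrifugation, a preparation that enriches hepatocytes without sorting them. The labels give 4 groups of 3 libraries, by antibody and day, and these groups were used as given. The labels do not say whether the libraries of a group came from separate animals, so every p-value measures only the spread between these samples, which may be technical.

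The authors deposited whole-number read counts per gene, not normalized, in 1 table with a gene identifier and a symbol on each line. The submitters' processing notes name cutadapt, STAR, HTSeq and DESeq2 and the mouse genome build GRCm38; versions, parameters, the annotation release and the strand setting are not given in the sources used here. All deposited values were whole and the column totals differed. All 12 columns were matched to samples by their titles and 0 columns were left over. The table listed 18227 genes, and no line named anything other than a gene. The lowest of the genes' highest counts was 6; how genes were chosen for the table is not given in the sources used here. GENCODE release M21 (GRCm38) held 18208 of the identifiers and gave 17959 of them the same symbol; coordinates come from it. In 15 cases a symbol stood for 2 identifiers, and the one with more counts kept the symbol.

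Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with few counts were removed with filterByExpr, which left 15294 genes, 13922 of them protein coding. Libraries were scaled by the trimmed mean of M-values (TMM), and a robust quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, which then share 1 estimate of the spread. Its test gave log2 fold changes, p-values adjusted by the Benjamini-Hochberg method over all genes tested, and a threshold of 0.05 on the adjusted p. Standard errors are the log2 fold change divided by the square root of the F statistic. The 5 comparisons were anti-Gr1 against isotype at POD1, the same at POD2, the difference between these effects (an interaction), and POD2 against POD1 within each antibody. Expression levels are CPM values with TMM-scaled library sizes, given as mean ± SD, and shares of a library's counts are percentages of its total. Log2 CPM used a prior count of 1.

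Gene lists were tested with camera (limma 3.58.1) on lists of at least 5 measured genes. The preset correlation between genes was 0.01; the test was repeated with a correlation estimated from the data. Adjusted p-values of lists are over the 35 lists, and those of lists added later over the 7 added. The lists were chosen from textbook knowledge before the data were examined, together with the groups, the tests, the alternatives and the rule for named genes. They cover the cell cycle (DNA replication and G1/S; mitosis and G2/M; p53 targets and cell-cycle inhibitors), acute responses (acute phase; immediate early; NF-kB and TNF targets; interferon-stimulated; antigen presentation; ER stress; oxidative stress), hepatocyte functions (plasma proteins and hepatocyte transcription factors; cholesterol synthesis; fatty acid and triglyceride synthesis; fatty acid oxidation and ketogenesis; bile acids; xenobiotic metabolism; gluconeogenesis; glycolysis and hypoxia targets; urea cycle and amino acid catabolism; pericentral genes; periportal genes), growth (ribosome biogenesis; regeneration growth factors and receptors; YAP targets and fetal or progenitor genes), mitochondrially encoded genes, and markers of other cells (neutrophil; monocyte; Kupffer cell; sinusoidal endothelium; stellate cell; T and NK cell; B and plasma cell; cholangiocyte; erythroid; platelet). A further 7 lists were added after seeing the data: pancreatic acinar, pancreatic islet, adrenal steroid, adipocyte, skeletal muscle, early granule and mature neutrophil genes.

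Named genes follow a rule with 3 parts. The first takes, per comparison and direction, the 10 called genes with the largest fold change whose groups do not overlap and whose mean log2 CPM is at least 1, without predicted genes and pseudogenes. Where fewer than 5 pass, the genes with the smallest p fill up to 5 and are given as not passing. The second takes up to 4 members per list with the smallest p. The third is a set of 26 genes: Ly6g, Ly6c1, Ly6c2, S100a8, S100a9, Ccnd1, Ccna2, Ccnb1, Cdk1, Mki67, Foxm1, Pcna, Myc, Cdkn1a, Socs3, Saa1, Lcn2, Hp, Cyp7a1, Alb, Hnf4a, Vegfa, Met, Egfr, Igfbp1 and Il6ra. Some genes that the rule takes are not reported here. Genes outside the rule, or outside it for the comparison given, were chosen after their values were seen.

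Replicates were compared before use by a chi-square of their counts per gene, over 13443 genes with a mean count of at least 20. A near-identical pair within a group was averaged and counted as 1 sample in means and SDs, which leaves n = 3 at POD1 and n = 2 at POD2. The test kept all 12 libraries, so fold changes, SEs and p-values count these libraries separately. Folds can thus differ from the ratio of the means. The shared spread, and with it SEs and p-values in every comparison, is too small if near-identical libraries are not separate animals. Alternatives were DESeq2 1.42.0, limma-voom, no scaling factors, upper-quartile scaling, scaling without the 50 most abundant genes, no filter, a filter of at least 1 CPM in 3 libraries, a test against a log2 change of 0.5 (glmTreat), fits of the 2 groups compared alone, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were summing the near-identical pairs within groups ("pairs merged"), leaving out the pair that crosses the days ("cross-day pair out"), both changes together, a pancreatic acinar score as a covariate, and removal of acinar genes. With the cross-day pair out the anti-Gr1 POD2 group holds only its near-identical replicates 1 and 2. They count as 2 libraries, as does the near-identical pair of isotype POD2. The spread is therefore too small if they are not separate animals. With both changes together the anti-Gr1 POD2 group holds 1 library, which is assumed to vary like the other groups.

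The procedure after filtering was tested on simulated counts with 200 changed genes per comparison among 15294 genes, drawn from the real means, spreads and library sizes. Each library was drawn independently, so the simulation held no near-identical pairs. Its 200 changed genes are also far fewer than the 6404 called at POD2, so its recovery need not be that of the real comparisons. Between 3 and 9 unchanged genes were called per comparison. It recovered 16% of the 2-fold and 70% of the 4-fold changes for anti-Gr1 against isotype at POD1, and 26% and 69% at POD2. For the difference of effects it recovered 6% and 60%. For POD2 against POD1 it recovered 28% and 69% in the isotype groups and 29% and 80% in the anti-Gr1 groups. Reads shared between close paralogs (stefin A genes, Ly6c1 and Ly6c2, hemoglobin chains, major urinary proteins, trypsins) and overlapping genes on opposite strands could not be separated, so single values within those families are uncertain.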

Results

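Hepatocyte-enriched cells from the remnant livers of mice after 70% hepatectomy were profiled by RNA sequencing in 12 libraries, 3 for each combination of antibody (anti-Gr1 or isotype) and day (POD1 or POD2). Gr1 is an antigen of granulocytes made up of the product of Ly6g, with cross-binding to that of Ly6c2 and Ly6c1, and the stated purpose of the antibody was to remove granulocytic myeloid-derived suppressor cells. Total counts per library lay between 13189392 and 15822043. The scaling factors ranged from 0.602 in isotype POD2 replicate 3 to 1.28 in isotype POD1 replicate 1. The first 3 principal components held 54.2%, 12.7% and 11.5% of the variance.

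A pair of isotype POD2 libraries, replicates 1 and 2, differed by little more than counting noise, with a chi-square per gene of 1.70 where 1 is the value for counting noise alone. Replicates 1 and 2 of anti-Gr1 POD2 gave 6.17. Replicate 3 of anti-Gr1 POD1 and replicate 3 of anti-Gr1 POD2, which carry different days, gave 3.92. The remaining 63 pairs of libraries lay at 70.5 or above, among them 10 pairs of the same group that reached up to 482. Each near-identical pair within a group was counted as 1 sample in means and SDs, so that n = 3 at POD1 and n = 2 at POD2. Counts of changed genes are also given with these pairs merged, with the cross-day pair left out, and with both changes, all chosen after seeing the data. With only the cross-day pair out, near-identical libraries still count separately in the isotype and anti-Gr1 POD2 groups.

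**Figure D1:**
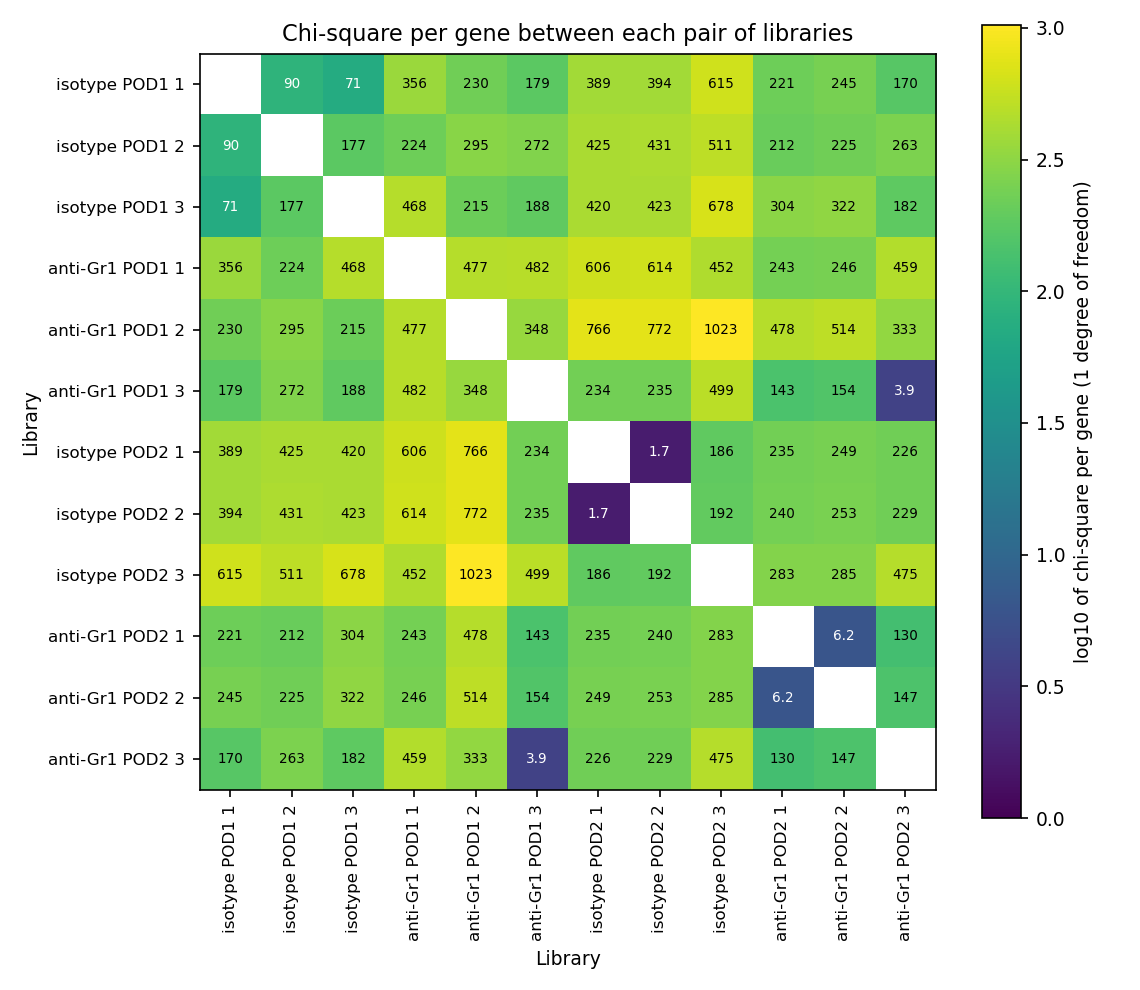
Chi-square per gene between the counts of each pair of libraries, over 13443 genes, with both axes listing the 12 libraries by group and replicate and the colour scale giving its log10. The 3 near-identical pairs stand at 1.70, 6.17 and 3.92, and all 63 others at 70.5 or more.

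Transcripts of pancreatic acinar cells, digestive enzymes that hepatocytes do not make, took a share of each library that varied within every group. Acinar genes took 3.11%, 9.19% and 0.0123% of the counts in the isotype POD1 libraries, 7.06%, 6.97% and 26.4% in isotype POD2, 21.7%, 0.153% and 2.46% in anti-Gr1 POD1, and 11.6%, 12.3% and 2.42% in anti-Gr1 POD2. Ctrb1 (ENSMUSG00000031957, chymotrypsinogen, GRCm38 chromosome 8, 111686519 to 111691010) spanned 19.3 to 109300 CPM. Genes of plasma proteins and hepatocyte transcription factors took 1.16% to 2.11% of the counts in isotype POD1, 9.43% to 12.3% in isotype POD2, 0.407%, 0.532% and 4.56% in anti-Gr1 POD1, and 3.51% to 4.50% in anti-Gr1 POD2.

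The genes of the antibody's target were read first, as a check of the labels. Ly6g (ENSMUSG00000022582, a protein-coding gene of neutrophils, GRCm38 chromosome 15, 75155240 to 75159126) stood at 0.247 to 1.98 CPM in the 6 isotype libraries and at 24.2 to 54.9 CPM in the 6 libraries labelled anti-Gr1. Its neighbours Ly6c2 (ENSMUSG00000022584, 75108158 to 75111970), a surface protein of monocytes, and Ly6c1 (ENSMUSG00000079018, 75044018 to 75048830), also of endothelium, are close paralogs whose reads may be shared. The target's transcript was thus higher where the label names its removal. The groups are called the libraries labelled anti-Gr1 for this reason, and every direction given here rests on those labels.

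**Figure D2:**
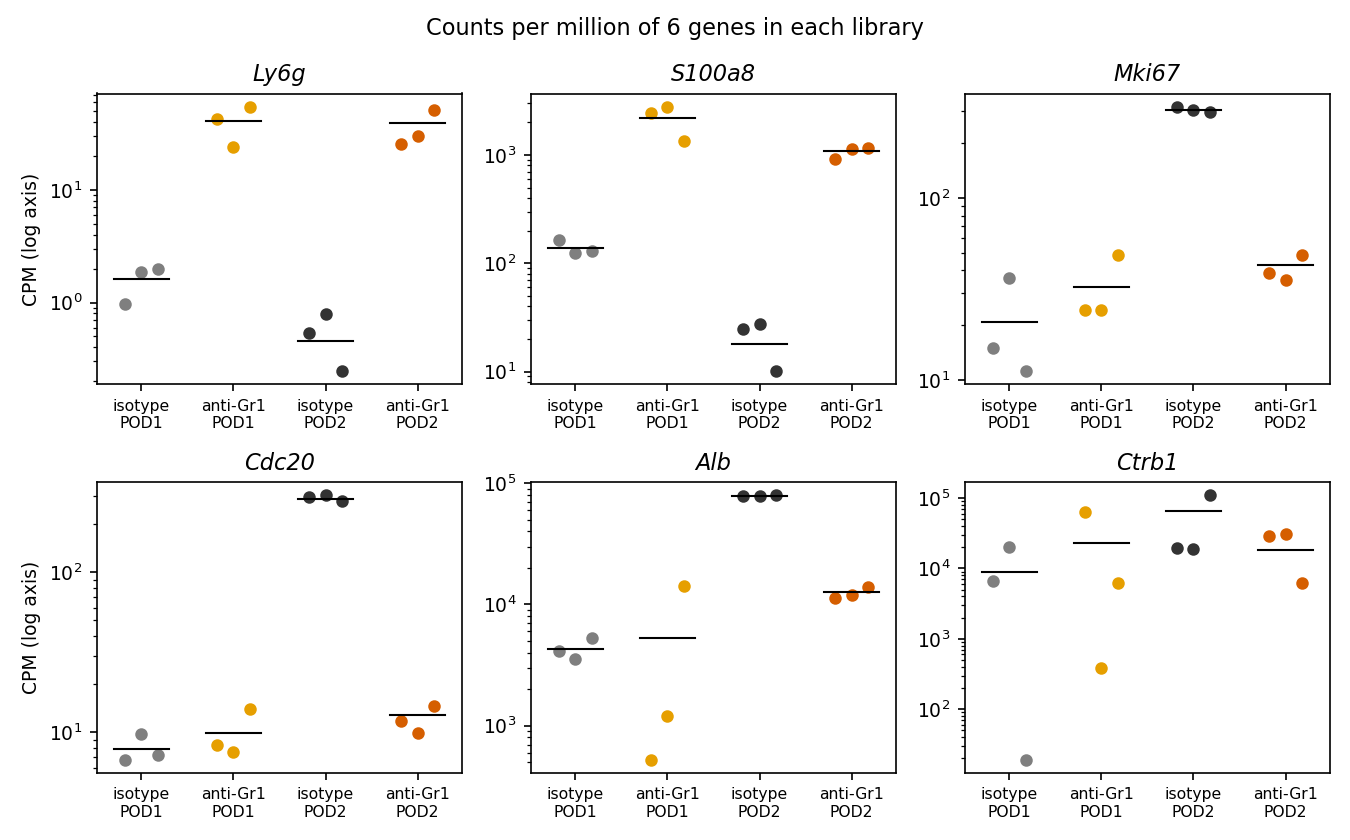
CPM of Ly6g, S100a8, Mki67, Cdc20, Alb and Ctrb1 in each of the 12 libraries on log axes, with a horizontal line at the group mean in which a near-identical pair counts once. Ly6g and S100a8 separate by antibody on both days, Mki67 and Cdc20 stand apart only in the isotype POD2 libraries, and Ctrb1 varies within groups.

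The comparison of antibodies at POD1 sets the libraries labelled anti-Gr1 against isotype 1 day after surgery. Granulocyte transcripts were higher in the libraries labelled anti-Gr1. Of the 29 measured neutrophil and granulocytic myeloid markers, 21 rose, 0 fell and 8 did not pass. Adjusted over the list alone 22 rose, and the median log2 fold change was 3.18 (camera adjusted p = 3.57e-75, adjusted p = 0.00934 with an estimated correlation). Stfa2, a stefin of granulocytes with close paralogs, rose 160-fold, from 1.23 ± 0.401 to 198.6 ± 94.5 CPM (SD, n = 3 each; log2 fold change 7.32 ± 0.41 SE, adjusted p = 1.5e-05). Ngp (ENSMUSG00000032484, neutrophilic granule protein, GRCm38 chromosome 9, 110419747 to 110423012) rose 58.3-fold, from 16.3 ± 5.87 to 949 ± 276 CPM (log2 fold change 5.87 ± 0.42, adjusted p = 7.35e-05).

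Ltf, lactoferrin of secondary granules (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), rose by 5.62 ± 0.45 on the log2 scale (SE, adjusted p = 0.000174), and Ly6g by 4.67 ± 0.44 (adjusted p = 0.000457). S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035) and S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), which encode calprotectin, rose by 3.98 ± 0.42 and 3.18 ± 0.39 (adjusted p = 0.000862 and 0.0026). S100a9 reached 3252 ± 960 CPM against 358 ± 42.6 CPM. Cd177, Camp, Stfa3, BC100530, Olfm4, Retnlg and Padi4, all genes of granulocytes, rose by log2 fold changes between 2.30 (Padi4) and 7.04 (BC100530). Gpnmb, a glycoprotein of macrophages, and Atp6v0d2, a proton pump subunit, rose by 4.72 ± 0.60 and 4.78 ± 0.40. These genes, Stfa2 and Ngp among them, passed in every alternative run for them. In the granulocyte list 18, 24 and 21 members rose with the pairs merged, the cross-day pair out, and both.

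Other myeloid and interferon-stimulated genes were also higher. Monocyte and recruited macrophage markers rose in 7 of 22, with 0 falling (14 and 0 adjusted over the list alone, median 1.03, camera adjusted p = 2.32e-12, adjusted p = 0.475 with an estimated correlation). Without anti-Gr1 POD1 replicate 2 the median of the monocyte and recruited macrophage markers was 0.66. Ms4a4c, a membrane protein of monocytes, rose by 2.49 ± 0.38 (SE, adjusted p = 0.00882) and Ly6c2 by 1.37 ± 0.20, from 9.31 ± 0.595 to 24.1 ± 2.04 CPM (adjusted p = 0.00593). Ly6c1 did not pass, at 0.40 ± 0.30 (adjusted p = 0.474). Of 37 interferon-stimulated genes, 12 rose and 0 fell (26 and 0 adjusted over the list alone, median 0.76, camera adjusted p = 1.56e-17, adjusted p = 0.475 with an estimated correlation). Merging the pairs left 1 of them, leaving out the cross-day pair gave 16, and both gave 5. Of 18 antigen presentation genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 0.00084, adjusted p = 0.809 with an estimated correlation). Merging the pairs, or both changes, gave 0. Antigen presentation had a median of 0.61 without isotype POD1 replicate 2. Among the interferon-stimulated genes Tap1, a peptide transporter of antigen presentation, rose by 1.12 ± 0.14 (adjusted p = 0.00332). The call of Ms4a4c was lost in a fit of the 2 groups alone (adjusted p = 0.125), that of Ly6c2 without scaling factors (adjusted p = 0.0503), and that of Tap1 in both (adjusted p = 0.0698 and 0.0552).

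Transcripts of red cells and of antibody-secreting cells were lower in the libraries labelled anti-Gr1 at POD1. Of 9 erythroid markers, 5 fell and 0 rose (8 and 0 adjusted over the list alone, median -4.23, camera adjusted p = 4.2e-08, adjusted p = 0.475 with an estimated correlation). Hbb-bs, a beta globin with a close paralog, was at 150 ± 56.8 CPM against 3475 ± 3930 CPM (SD, n = 3 each; log2 fold change -4.53 ± 0.81, adjusted p = 0.0183). The isotype libraries stood at 1644, 7990 and 792 CPM. Without isotype POD1 replicate 2 the median of the Erythroid markers was -2.60. The call of Hbb-bs was lost in a fit of the 2 groups alone (adjusted p = 0.167), with the pairs merged (0.0638) and with both changes (0.0599). No erythroid marker passed when the pairs were merged (0 of 9), with Hbb-bs still at -4.52. Of 14 B cell and plasma cell markers, 5 fell and 0 rose (13 and 0 adjusted over the list alone, median -1.94, camera adjusted p = 1.12e-10, adjusted p = 0.475 with an estimated correlation). With the pairs merged, the cross-day pair out, and both, 0, 7 and 4 fell. Iglc2, a light chain constant gene, fell by 2.46 ± 0.41 (adjusted p = 0.0125). Its call was lost with the pairs merged (0.0517) and in the fit of the 2 groups alone (0.137), and kept with both changes (0.0386).

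Mup16 and Mup17, major urinary proteins that hepatocytes secrete and that share reads with many paralogs, were the lowest hepatocyte genes that passed. Mup17 fell from 216.5 ± 71.2 to 33.8 ± 9.03 CPM (log2 fold change -2.68 ± 0.27 SE, adjusted p = 0.000598) and Mup16 from 64.8 ± 20.1 to 9.76 ± 2.44 CPM (-2.73 ± 0.27, adjusted p = 0.000598). Il6ra, a receptor subunit for interleukin 6, rose by 1.19 ± 0.16 (adjusted p = 0.0047), a call lost without scaling factors (adjusted p = 0.062) and in a fit of the 2 groups alone (0.0855).

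Lists of hepatocyte function at POD1 depended on single libraries. Several of their medians moved far without anti-Gr1 POD1 replicate 3, which is near-identical to a library labelled POD2. Alb (ENSMUSG00000029368, albumin, GRCm38 chromosome 5, 90460897 to 90476602) stood at 526, 1205 and 14110 CPM in the libraries labelled anti-Gr1 and at 4124, 3545 and 5270 CPM in isotype (log2 fold change 0.29 ± 0.95 SE, adjusted p = 0.89). Without anti-Gr1 POD1 replicate 3 and its partner Alb was at -2.31 and passed as lower (edgeR adjusted p = 0.00478). Of 36 xenobiotic metabolism genes, 0 rose and 1 fell (1 and 1 adjusted over the list alone). The median of the list was 0.36 and its mean 0.24, while camera gave a lower direction (adjusted p = 0.0352, adjusted p = 0.881 with an estimated correlation). With the cross-day pair out 32 fell, at a median of -2.24, and with both changes 24 fell. Xenobiotic metabolism lost its call without isotype POD1 replicate 1 (median 0.39) or 3 (0.49) and without anti-Gr1 POD1 replicate 1 (0.79), and camera gave a higher direction without anti-Gr1 POD1 replicate 2 (0.89). Pericentral hepatocyte genes had a median of 0.15, a mean of -0.03 and a lower direction by camera (adjusted p = 0.0224, adjusted p = 0.881 with an estimated correlation). Of its 22 genes 0 rose and 2 fell (0 and 4 adjusted over the list alone), and 16 fell with the cross-day pair out. This call of the Pericentral hepatocyte genes was lost without anti-Gr1 POD1 replicate 1 (median 0.36) or 2 (0.32).

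Amino acid and fatty acid catabolism moved down as lists without single genes passing. Urea cycle and amino acid catabolism had 0 of 30 genes passing (0 adjusted over the list alone, median -0.94, camera adjusted p = 5.8e-07, adjusted p = 0.833 with an estimated correlation). Leaving out the cross-day pair gave 23 falling genes. The median of Urea cycle and amino acid catabolism was -0.47 without anti-Gr1 POD1 replicate 2 and -1.92 without replicate 3. Fatty acid oxidation and ketogenesis had 0 of 31 passing over all genes and 5 falling adjusted over the list alone (median -0.62, camera adjusted p = 4e-05, adjusted p = 0.833 with an estimated correlation). Leaving out the cross-day pair gave 11 falling genes. Without anti-Gr1 POD1 replicate 2 the median of Fatty acid oxidation and ketogenesis was -0.38. Plasma proteins and hepatocyte transcription factors (0 of 28, median 0.14) and bile acid genes (0 of 22, median 0.28) were not called (adjusted p = 0.184 and 0.136). With the cross-day pair out 23 plasma protein genes and 15 bile acid genes fell, and with both changes 9 and 8.

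Cell-cycle lists held few changes at POD1. DNA replication and G1/S genes had 0 of 36 passing (0 adjusted over the list alone, median -0.07, camera adjusted p = 0.393). Of 36 mitosis and G2/M genes, 1 rose (0 adjusted over the list alone, median 0.36, camera adjusted p = 0.000587, adjusted p = 0.881 with an estimated correlation). This call was lost with the cross-day pair out and without anti-Gr1 POD1 replicate 3 alone, where the median of Mitosis and G2/M was 0.02. The median of Mitosis and G2/M was 0.22 without isotype POD1 replicate 3 and 0.57 without anti-Gr1 POD1 replicate 1. Mki67 (ENSMUSG00000031004, a marker of cycling cells, GRCm38 chromosome 7, 135689784 to 135716361) did not pass, at 32.2 ± 14.0 against 20.8 ± 13.5 CPM (log2 fold change 0.63 ± 0.40, adjusted p = 0.402).

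Further lists had camera calls at POD1 that single libraries ended. Genes of the acute phase response had 1 of 33 rising (1 adjusted over the list alone, median 1.15, camera adjusted p = 0.000794, adjusted p = 0.881 with an estimated correlation). Without anti-Gr1 POD1 replicate 3 the median of the Acute phase response was 0.06 and the call was lost. Stellate cell and fibroblast markers had 0 of 22 passing and 4 falling adjusted over the list alone (median -0.34, adjusted p = 0.00377, adjusted p = 0.809 with an estimated correlation). Stellate cell and fibroblast markers were at -0.18 and lost the call without anti-Gr1 POD1 replicate 1, and were at -0.71 without replicate 3. Mitochondrially encoded genes had 0 of 9 passing and 2 falling adjusted over the list alone (median -0.83, adjusted p = 0.00354, adjusted p = 0.833 with an estimated correlation). Mitochondrially encoded genes were at -0.49 without anti-Gr1 POD1 replicate 1, where the call was lost, and at -0.53 without isotype POD1 replicate 2. Calls at an adjusted p of 0.0352 for gluconeogenesis (median -0.58), periportal genes (-0.58), sinusoidal endothelial cells (-0.30) and T and NK cells (-1.01), and of 0.0324 for platelets (0.86), were each lost with an estimated correlation (adjusted p = 0.881, and 0.809 for platelets). Without isotype POD1 replicate 3 the medians were -0.04 for Gluconeogenesis, 0.09 for Periportal hepatocyte genes, -0.22 for Liver sinusoidal endothelial cell markers and 0.69 for Platelet markers, and without isotype POD1 replicate 2 that of T and NK cell markers was -0.49, all with the call lost. Without anti-Gr1 POD1 replicate 1 these 5 calls were lost too, at -0.39, -0.31, -0.15, 0.94 and -0.96. Leaving out anti-Gr1 POD1 replicate 2 ended the calls of Gluconeogenesis (-0.25), Periportal hepatocyte genes (-0.22) and Platelet markers (0.58). Leaving out anti-Gr1 POD1 replicate 3 ended those of Liver sinusoidal endothelial cell markers (-0.28), T and NK cell markers (-1.15) and Platelet markers (0.94), and moved Gluconeogenesis to -0.97 and Periportal hepatocyte genes to -1.51. Leaving out isotype POD1 replicate 2 also ended the call of Liver sinusoidal endothelial cell markers (-0.27).

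In all, 344 genes were higher and 181 lower in the libraries labelled anti-Gr1 at POD1 (525 of 15294 tested; edgeR quasi-likelihood test), 227 and 114 of them by at least 2-fold. The count was 115 with the pairs merged, 2301 with the cross-day pair out and 793 with both. Of 63 named genes called, 25, 63 and 43 kept their call. Leaving out isotype POD1 replicate 1, 2 or 3 gave 183, 176 and 124 genes, and leaving out anti-Gr1 POD1 replicate 1, 2 or 3 gave 978, 293 and 2407. Without scaling factors the split was 112 higher and 199 lower, with the median of all genes shifted by -0.14, and without the 50 most abundant genes it was 450 and 132. DESeq2 called 1280 genes, a fit of the 2 groups alone 52, and a test against a log2 change of 0.5 called 138. The POD1 libraries hold no near-identical pair among themselves, but the main fit shares its spread with the POD2 groups. That spread, and with it the p-values at POD1, is too small if the near-identical pairs of POD2 are not separate animals.

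The same comparison was made at POD2, 2 days after surgery. Genes of mitosis were lower in the libraries labelled anti-Gr1, in which the share of plasma protein transcripts was also lower. Of 36 measured mitosis and G2/M genes, 35 fell, 0 rose and 1 did not pass (35 adjusted over the list alone), at a median log2 fold change of -2.94 (camera adjusted p = 1.86e-46, adjusted p = 0.131 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, was 24.2-fold lower, at 12.8 ± 2.74 against 289 ± 15.8 CPM (SD, n = 2 each; log2 fold change -4.59 ± 0.27 SE, adjusted p = 5.21e-06). Cdk1 (ENSMUSG00000019942, the kinase that drives entry into mitosis, GRCm38 chromosome 10, 69335146 to 69352938) fell from 179.6 ± 0.0547 to 19.8 ± 5.31 CPM (-3.27 ± 0.25, adjusted p = 1.49e-05). SEs and p-values at POD2 count 3 libraries per group, unlike the n of the means. With the pairs merged the edgeR adjusted p was 0.00102 for Cdc20 and 0.00168 for Cdk1.

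Foxm1 (ENSMUSG00000001517, a transcription factor of mitotic genes, chromosome 6, 128362967 to 128376146) and Ccnb1 (ENSMUSG00000041431, cyclin B1, chromosome 13, 100778650 to 100786570) fell by 3.10 ± 0.31 and 3.31 ± 0.33 on the log2 scale (SE, adjusted p = 5.83e-05 for each). Mki67 fell from 304 ± 10 to 42.9 ± 8.06 CPM (-2.90 ± 0.43, adjusted p = 0.000515), and Aurka and Plk1, mitotic kinases, fell by 3.69 ± 0.23 and 3.28 ± 0.24. Of 36 DNA replication and G1/S genes, 32 fell and 0 rose (32 and 0 adjusted over the list alone, median -1.39, camera adjusted p = 1.34e-20, adjusted p = 0.275 with an estimated correlation). Tyms, which makes thymidylate, fell by 2.81 ± 0.16, Gins2, of the replicative helicase, by 2.12 ± 0.16, and Pcna, the polymerase clamp, by 1.15 ± 0.15 (adjusted p = 0.000241), or by 0.70 without scaling factors. With the pairs merged, the cross-day pair out, and both, 34, 35 and 33 mitosis genes and 22, 29 and 20 replication genes fell. Of 21 p53 targets and cell-cycle inhibitors, 2 rose and 8 fell (2 and 8 adjusted over the list alone, median -0.38, camera adjusted p = 0.0219, adjusted p = 0.542 with an estimated correlation). Among its falling members Cdkn2c, a kinase inhibitor, fell by 2.84 ± 0.21, and among its rising members Pmaip1, a death-promoting BH3 protein, rose by 2.04.

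Granulocyte transcripts were higher again. Of 29 neutrophil and granulocytic myeloid markers, 26 rose and 1 fell (26 and 2 adjusted over the list alone, median 4.92, camera adjusted p = 4.62e-35, adjusted p = 0.0379 with an estimated correlation). Ngp rose from 1.79 ± 0.792 to 545 ± 153 CPM (SD, n = 2 each). Its log2 fold change in the fit of all 12 libraries was 7.98 ± 0.47 (SE, adjusted p = 5.21e-06). Ly6g rose 64.3-fold in that fit (6.01 ± 0.51, adjusted p = 2.53e-05), with means of 0.455 ± 0.295 and 39.7 ± 16.8 CPM. S100a8 rose from 18.0 ± 11.2 to 1087 ± 91.9 CPM (5.69 ± 0.46, adjusted p = 1.87e-05). BC117090, another stefin gene, had 1 count over the isotype POD2 libraries and 1073 over those labelled anti-Gr1. The member that fell was Prtn3, proteinase 3 of neutrophil granules, chosen after its value was seen (-1.53 ± 0.34, adjusted p = 0.00476). Ly6c2 and Ly6c1 rose by 2.81 ± 0.22 and 1.87 ± 0.32.

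Markers of other non-parenchymal cells were higher at POD2 as well, in the libraries with the lower share of plasma protein transcripts. Liver sinusoidal endothelial cell markers rose in 25 of 26, with 0 falling (26 and 0 adjusted over the list alone, median 1.27, camera adjusted p = 7.57e-09, adjusted p = 0.542 with an estimated correlation), but in 5 with both changes. Bmp2, an endothelial signal to hepatocytes, rose from 57.4 ± 4.87 to 213.5 ± 67.8 CPM (SD, n = 2 each; 1.75 ± 0.27 SE, adjusted p = 0.000571), and Oit3 rose by 1.89 ± 0.27. Kupffer cell and macrophage markers rose in 19 of 22 and fell in 1 (21 and 1 adjusted over the list alone, median 1.52, camera adjusted p = 3.68e-09, adjusted p = 0.542 with an estimated correlation). Monocyte and recruited macrophage markers rose in 18 of 22 (18 adjusted over the list alone, median 2.02, camera adjusted p = 4.22e-10, adjusted p = 0.542 with an estimated correlation). Adgre1, the F4/80 antigen, rose by 2.44 ± 0.33, and Ptprc, the antigen of all leukocytes, by 2.96 ± 0.32, from 16.2 ± 7.91 to 147 ± 25.1 CPM. T and NK cell markers rose in 7 of 20 (7 adjusted over the list alone, median 0.71, camera adjusted p = 0.00349, adjusted p = 0.676 with an estimated correlation), among them the granzymes Gzma and Gzmb. The median of the T and NK cell markers was 1.53 without isotype POD2 replicate 3. Platelet markers rose in 4 of 10 (4 adjusted over the list alone, median 0.83, camera adjusted p = 0.0262, adjusted p = 0.676 with an estimated correlation). Platelet markers lost the list call without isotype POD2 replicate 3 (0.93) or anti-Gr1 POD2 replicate 3 (0.66). With both changes 10 Kupffer cell, 15 monocyte and 3 T and NK cell markers rose.

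Inflammatory and interferon lists were higher. Of 37 interferon-stimulated genes 25 rose (27 adjusted over the list alone, median 0.95, camera adjusted p = 1.36e-08, adjusted p = 0.546 with an estimated correlation). Of 18 antigen presentation genes 16 rose (17 adjusted over the list alone, median 1.26, camera adjusted p = 2.68e-05, adjusted p = 0.542 with an estimated correlation). Under both changes 12 and 1 rose. Irf7, a regulator of interferon genes, rose by 2.31 ± 0.32 (SE, adjusted p = 0.00035) and H2-Ab1, a class II antigen, by 1.86. NF-kB and TNF targets rose in 11 of 26 (14 adjusted over the list alone, median 1.24, camera adjusted p = 0.000228, adjusted p = 0.676 with an estimated correlation). Immediate early genes rose in 9 of 24 (9 adjusted over the list alone, median 0.68, camera adjusted p = 0.0106, adjusted p = 0.718 with an estimated correlation). In either list 0 fell, and 2 and 3 rose under both changes. Birc3, an NF-kB target, rose by 2.00 and Klf4, an immediate early transcription factor, by 1.64.

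Several lists of hepatocyte metabolism were lower, in the libraries with the lower share of plasma protein transcripts. A smaller share of hepatocytes in the preparation therefore cannot be told apart from a change within cells. Cholesterol synthesis fell in 14 of 24 genes and rose in 0 (15 and 0 adjusted over the list alone, median -1.23, camera adjusted p = 2.04e-05, adjusted p = 0.676 with an estimated correlation). Pmvk, of the mevalonate pathway, stood at -1.82 ± 0.16 (SE, adjusted p = 3.08e-05), and 8 genes fell with both changes. Fatty acid oxidation and ketogenesis fell in 15 of 31 (15 adjusted over the list alone, median -0.78, camera adjusted p = 0.000465, adjusted p = 0.676 with an estimated correlation). With both changes 1 gene of the list fell. Fatty acid and triglyceride synthesis fell in 9 of 22 and rose in 1 (9 and 1 adjusted over the list alone, median -0.88, camera adjusted p = 0.0123, adjusted p = 0.676 with an estimated correlation). With both changes 4 fell and 0 rose. Xenobiotic metabolism fell in 8 of 36 (7 adjusted over the list alone, median -1.60, camera adjusted p = 0.00121, adjusted p = 0.718 with an estimated correlation). The number was 29 with the cross-day pair out. Gstm1, a glutathione transferase, fell by 2.82 ± 0.40 (adjusted p = 0.000416) and Ephx1, an epoxide hydrolase, by 1.71 ± 0.28. Pericentral hepatocyte genes fell in 7 of 22 and rose in 1 (5 and 1 adjusted over the list alone, median -1.02, camera adjusted p = 0.0178, adjusted p = 0.718 with an estimated correlation). Plasma proteins and hepatocyte transcription factors fell in 6 of 28 (0 adjusted over the list alone, median -1.16, camera adjusted p = 0.01, adjusted p = 0.718 with an estimated correlation). The number was 0 with the pairs merged and 21 with the cross-day pair out. Alb did not pass (-2.66 ± 1.01, adjusted p = 0.0553), nor with the pairs merged (0.218). It passed with the cross-day pair out (-2.75, adjusted p = 0.000706), where near-identical libraries still count separately. With both changes Alb stood at -2.76. Urea cycle and amino acid catabolism fell in 3 of 30 (0 adjusted over the list alone, median -1.08, camera adjusted p = 0.0182, adjusted p = 0.749 with an estimated correlation). Ribosome biogenesis fell in 10 of 26 (9 adjusted over the list alone, median -0.19, camera adjusted p = 0.0262, adjusted p = 0.718 with an estimated correlation). Ribosome biogenesis lost the list call, with a median of 0.26, without scaling factors, at -0.12 with the cross-day pair out and at -0.09 without isotype POD2 replicate 3, and the median was -0.12 without anti-Gr1 POD2 replicate 3.

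The remaining lists were not called at POD2, and their counts adjusted over the list alone were the same unless given. Genes of the acute phase response rose in 5 of 33 (3 adjusted over the list alone, median 0, mean 0.31, camera adjusted p = 0.455), regeneration growth factors and receptors rose in 12 and fell in 2 of 32 (median 0.05, adjusted p = 0.144). Glycolysis and hypoxia targets rose in 11 and fell in 6 of 27 (median 0.26, adjusted p = 0.18). YAP targets and fetal or progenitor genes rose in 8 and fell in 3 of 21 (median 0.33, adjusted p = 0.481), oxidative stress genes rose in 5 and fell in 11 of 21 (median -0.74, adjusted p = 0.214). Stellate cell and fibroblast markers rose in 6 of 22 (median 0.56, adjusted p = 0.0691). Bile acid genes rose in 1 and fell in 3 of 22 (1 and 2 adjusted over the list alone, median -0.90, adjusted p = 0.192), periportal genes rose in 2 and fell in 4 of 21 (median -0.76, adjusted p = 0.365). Gluconeogenesis fell in 1 of 13 (median -0.26, adjusted p = 0.481). ER stress genes fell in 2 of 24 (0 adjusted over the list alone, median -0.10, adjusted p = 0.479), B cell and plasma cell markers rose in 3 of 14 (1 adjusted over the list alone, median 1.09, adjusted p = 0.112) and cholangiocyte markers in 2 of 16 (median 0.43, adjusted p = 0.185). Erythroid markers (median 0.13, adjusted p = 0.959) and mitochondrially encoded genes (median -0.19, adjusted p = 0.612) had 0 of 9 passing each, against medians of -4.23 and -0.83 at POD1.

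**Figure D3:**
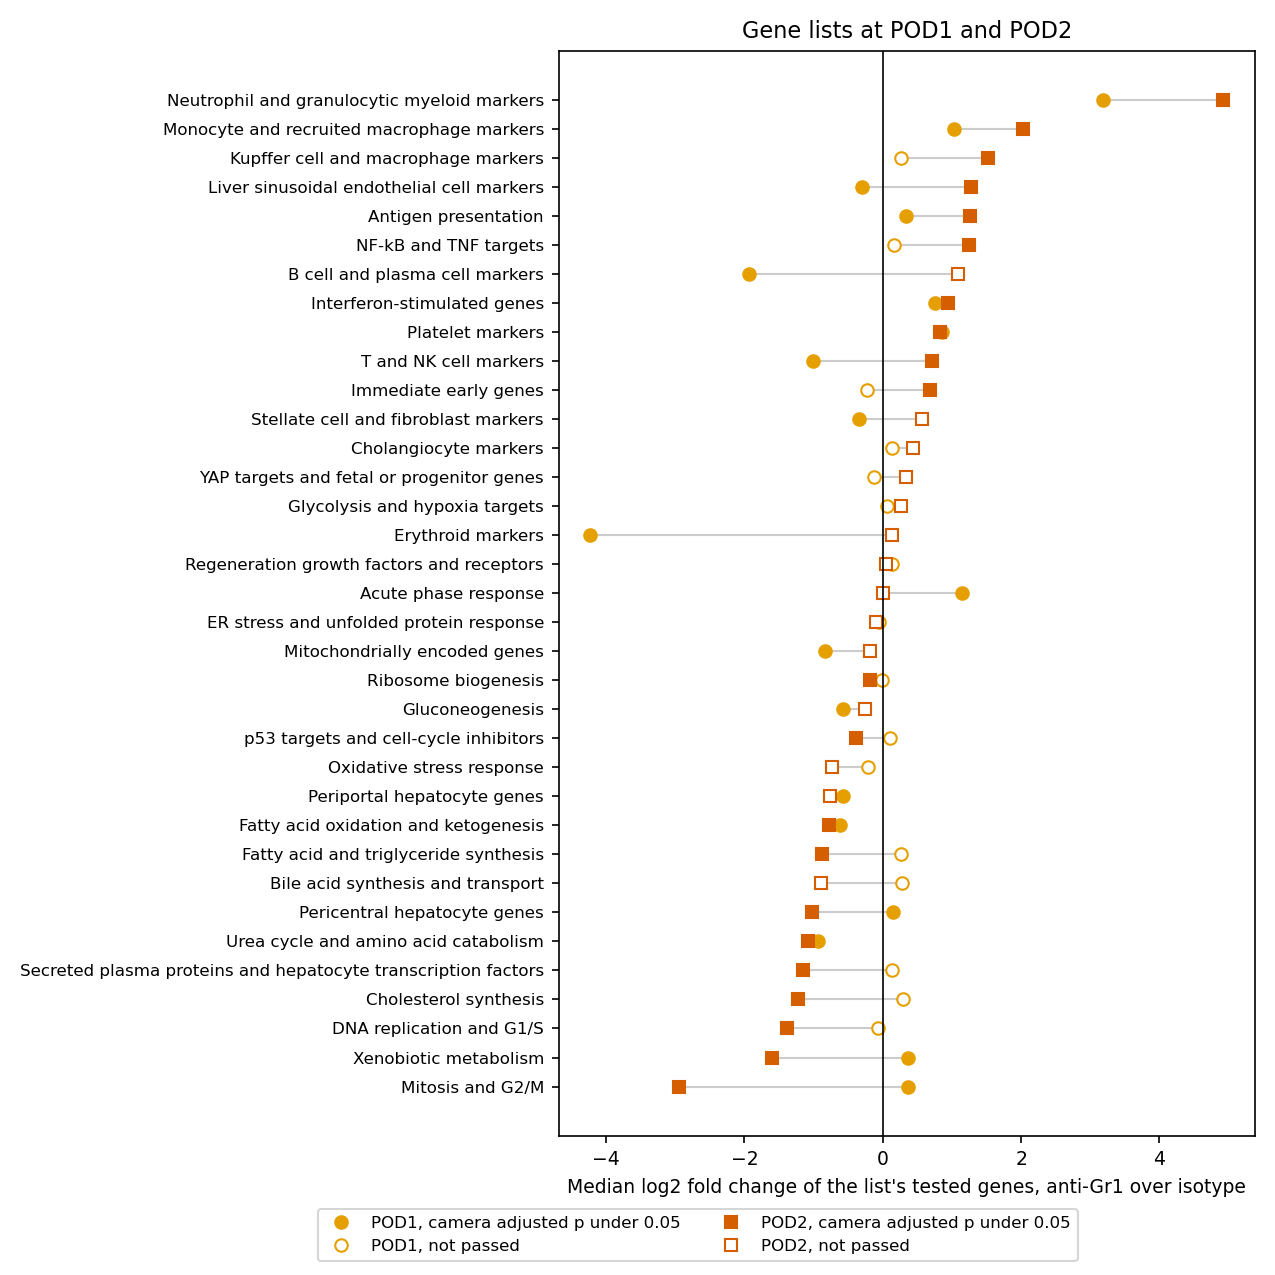
Median log2 fold change of the tested genes of each of the 35 lists, libraries labelled anti-Gr1 over isotype, with circles for POD1, squares for POD2 and filled symbols where the camera adjusted p was under 0.05. Mitosis and G2/M stands at 0.36 and -2.94, and neutrophil and granulocytic myeloid markers at 3.18 and 4.92.

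In all, 3183 genes were higher and 3221 lower at POD2 (6404 of 15294; edgeR), 1971 and 1359 of them by at least 2-fold. With the pairs merged the count was 3960 (2518 higher and 1442 lower), with the cross-day pair out 6338, and with both 1650, and of 159 named genes called 134, 156 and 106 kept their call. The balance of directions moved with the scaling and with 1 library. Leaving out isotype POD2 replicate 3 gave 3016 higher and 1881 lower genes. Without scaling factors the split was 4994 and 1103 and the median of all genes shifted by 0.45, and without the 50 most abundant genes it was 3813 and 2565 with a shift of 0.12. A test against a log2 change of 0.5 called 3289. With 1 library of the cross-day pair in each, the calls of the 2 days shared 257 higher genes, where independent lists would share 71.6, and 73 lower genes, where they would share 38.1, and 39 genes were called in opposite directions.

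Whether the effect of the antibody differed between the days was tested as an interaction, in which positive values are a higher effect at POD2. Mitosis and G2/M genes differed between the days, with 35 of 36 lower and 0 higher (35 and 0 adjusted over the list alone, median -3.41, camera adjusted p = 1.08e-72, adjusted p = 0.0921 with an estimated correlation). Cdc20 was at -4.93 ± 0.35 (SE, adjusted p = 0.000134), Iqgap3, a scaffold of dividing cells, at -4.57 ± 0.41, Cenpm, of the centromere, at -4.15 ± 0.33 and Cdk1 at -3.51 ± 0.33 (adjusted p = 0.00026). Of 36 DNA replication and G1/S genes, 22 were lower (25 adjusted over the list alone, median -1.38, camera adjusted p = 3.59e-21, adjusted p = 0.365 with an estimated correlation). With both changes 19 mitosis and 2 replication genes were lower. Liver sinusoidal endothelial cell markers were higher in 22 of 26 (24 adjusted over the list alone, median 1.60, camera adjusted p = 1.11e-13, adjusted p = 0.454 with an estimated correlation). B cell and plasma cell markers were higher in 11 of 14 (14 adjusted over the list alone, median 2.67, camera adjusted p = 6.57e-08, adjusted p = 0.454 with an estimated correlation). With both changes 0 of either were higher. Bmp2 stood at 2.23 ± 0.37 (adjusted p = 0.00387), and at 1.96 with both changes (adjusted p = 0.13). Neutrophil and granulocytic myeloid markers were higher in 11 of 29 and lower in 1 (16 and 2 adjusted over the list alone, median 1.63, camera adjusted p = 3.7e-06, adjusted p = 0.498 with an estimated correlation). With both changes the numbers were 0 and 1.

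The difference between the days passed in 2539 genes (1358 higher and 1181 lower; edgeR), with 877 when the pairs were merged, 2030 with the cross-day pair out and 76 with both. Of 115 named genes called, 49, 88 and 16 kept their call. Without scaling factors the split was 2904 and 292 with the median of all genes shifted by 0.59, and with upper-quartile scaling 1639 and 913. Leaving out isotype POD1 replicate 2 gave 1674 genes, isotype POD2 replicate 1, 2 or 3 gave 1681, 1580 and 1684, anti-Gr1 POD1 replicate 2 gave 4187, and anti-Gr1 POD2 replicate 1 or 2 gave 1420 and 1678. A test against a log2 change of 0.5 called 900.

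Between POD1 and POD2, the isotype groups were compared for the course of regeneration in mice given the isotype antibody. The share of plasma protein transcripts in these libraries was 1.2% to 2.1% at POD1 and 9.4% to 12.3% at POD2. A change in the share of hepatocytes in the preparation therefore cannot be told apart from a change within cells. Mitosis and G2/M genes rose in 35 of 36 and fell in 0 (35 and 0 adjusted over the list alone, median log2 fold change 3.74, camera adjusted p = 7.95e-59, adjusted p = 0.17 with an estimated correlation). Cdc20 rose 37.2-fold, from 7.88 ± 1.60 (SD, n = 3) to 289 ± 15.8 CPM (n = 2; log2 fold change 5.22 ± 0.28 SE, adjusted p = 4.97e-06), and Mki67 from 20.8 ± 13.5 to 304 ± 10 CPM (3.88 ± 0.45, adjusted p = 0.00013). DNA replication and G1/S genes rose in 29 of 36 (30 adjusted over the list alone, median 1.64, camera adjusted p = 4.54e-19, adjusted p = 0.302 with an estimated correlation), with Tyms at 2.63 ± 0.16 and Tk1, thymidine kinase, at 2.67.

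Hepatocyte functions rose with them. Cholesterol synthesis rose in 23 of 24 genes (24 adjusted over the list alone, median 2.37, camera adjusted p = 3.09e-15, adjusted p = 0.302 with an estimated correlation). Fdft1, squalene synthase, stood at 2.76 ± 0.31 (SE, adjusted p = 9.56e-05). Plasma proteins and hepatocyte transcription factors rose in 23 of 28 (25 adjusted over the list alone, median 2.93, camera adjusted p = 8.32e-06, adjusted p = 0.564 with an estimated correlation). Xenobiotic metabolism rose in 28 of 36 (31 adjusted over the list alone, median 2.87, camera adjusted p = 1.08e-06, adjusted p = 0.564 with an estimated correlation). In either list 10 rose with the pairs merged. Alb rose from 4313 ± 878 to 78780 ± 1220 CPM (4.19 ± 1.09, adjusted p = 0.00968) and Apoa1, the main protein of high-density lipoprotein, from 1635 ± 423 to 14830 ± 1160 CPM (3.15 ± 0.64, adjusted p = 0.00262). DESeq2 gave no adjusted p for 18 of the named genes called here, Alb among them. Fatty acid and triglyceride synthesis rose in 15 of 22 (16 adjusted over the list alone, median 1.56, camera adjusted p = 7.1e-06, adjusted p = 0.423 with an estimated correlation), with Srebf1, its transcription factor, at 2.47 ± 0.27.

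Markers of endothelial cells, Kupffer cells and granulocytes fell from POD1 to POD2 in the isotype libraries, and those of cholangiocytes were not called (median 0.34, camera adjusted p = 0.873; 1 of 16 rose and 3 fell). Liver sinusoidal endothelial cell markers fell in 26 of 26 (26 adjusted over the list alone, median -1.89, camera adjusted p = 2.34e-15, adjusted p = 0.302 with an estimated correlation). Kupffer cell and macrophage markers fell in 21 of 22 (21 adjusted over the list alone, median -2.11, camera adjusted p = 4.36e-13, adjusted p = 0.302 with an estimated correlation). Neutrophil and granulocytic myeloid markers fell in 24 of 29, with 2 rising (26 and 2 adjusted over the list alone, median -2.61, camera adjusted p = 8.88e-10, adjusted p = 0.302 with an estimated correlation). Bmp2 fell from 372 ± 114 to 57.4 ± 4.87 CPM (-2.67 ± 0.27 SE, adjusted p = 6.52e-05), Vsig4, a complement receptor of Kupffer cells, by 2.59 ± 0.29, and S100a8 from 139 ± 20.5 to 18.0 ± 11.2 CPM (-2.75 ± 0.40, adjusted p = 0.000383). NF-kB and TNF targets fell in 20 of 26 (21 adjusted over the list alone, median -1.67, camera adjusted p = 7.1e-06, adjusted p = 0.564 with an estimated correlation). The chemokine Ccl2 stood at -2.70 and the cytokine Il1a at -2.50. Over all genes 3514 were higher and 3580 lower at POD2 (7094 of 15294; edgeR), or 5058, 7637 and 5429 with the pairs merged, the cross-day pair out, and both. Of 172 named genes called, 152, 172 and 164 kept their call. Without scaling factors the split was 978 and 7497, with the median of all genes shifted by -0.69, and with the pairs merged 1979 and 3079. A test against a log2 change of 0.5 called 4143.

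In the libraries labelled anti-Gr1 no gene passed between POD1 and POD2. edgeR called 0 of 15294 genes, with 2352 at an unadjusted p under 0.05 and a smallest adjusted p of 0.287, limma-voom called 0 and DESeq2 91. Mki67 was at 42.9 ± 8.06 CPM at POD2 (SD, n = 2) and 32.2 ± 14.0 at POD1 (n = 3; log2 fold change 0.35 ± 0.40 SE, adjusted p = 0.66), Alb at 1.23 ± 0.97 on the log2 scale (adjusted p = 0.519) and Ly6g at -0.18 ± 0.36 (adjusted p = 0.799). The smallest p-values belonged to genes such as Col6a6, a collagen chain (1.83 ± 0.36), and Ccl24, a chemokine (-1.71 ± 0.38), at an adjusted p of 0.287 each. With the cross-day pair out 1657 genes were higher and 907 lower, and with both changes 530 and 15. Leaving out anti-Gr1 POD1 replicate 3 gave 2900 genes and leaving out anti-Gr1 POD2 replicate 3 gave 68. With both changes Alb was at 3.76 (adjusted p = 0.0143) and Ccl24 at -2.50 (adjusted p = 0.00274).

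As lists, hepatocyte functions stood higher and myeloid markers lower at POD2 in these libraries, with 0 single genes passing in any. Here too a change in the share of hepatocytes cannot be told apart from a change within cells. Camera called xenobiotic metabolism (median 1.11, 0 of 36 adjusted over the list alone) and cholesterol synthesis (0.92, 6 of 24), at an adjusted p of 2.18e-13 each, and adjusted p = 0.402 with an estimated correlation for each. Kupffer cell and macrophage markers (median -0.76, 14 of 22 lower adjusted over the list alone) and monocyte and recruited macrophage markers (-1.05, 15 of 22) were lower (adjusted p = 3.43e-09 and 3.39e-11, and adjusted p = 0.402 with an estimated correlation for each). The median of Xenobiotic metabolism was 0.68, 0.56 and 3.91 without anti-Gr1 POD1 replicate 1, 2 or 3, and that of Cholesterol synthesis 0.61 and 1.39 without replicate 1 or 3. Without replicate 2 the medians of Kupffer cell and macrophage markers and Monocyte and recruited macrophage markers were -0.50 and -0.57. DNA replication and G1/S genes (median 0.09, adjusted p = 0.154) were not called. Mitosis and G2/M genes had a median of 0.29 (adjusted p = 0.000558, adjusted p = 0.578 with an estimated correlation), and the call of Mitosis and G2/M was lost without anti-Gr1 POD1 replicate 1 (0.13) or 2 (0.12) or anti-Gr1 POD2 replicate 3 (0.14).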

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

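Several tests were chosen after the results were seen. They set granulocyte against Kupffer cell scores, mitotic against plasma protein scores and labels against an exchange, and compared scores of other tissues. The settings with pairs merged, the cross-day pair out or an acinar covariate were also chosen then.

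The antibody effect differed between the days, by the interaction test, in 2539 genes. Of the 35 lists, 19 differed by camera with the preset correlation, and with an estimated correlation none did. Medians of the log2 difference were negative for mitosis and G2/M (-3.41), DNA replication and G1/S (-1.38), p53 targets and cell-cycle inhibitors (-0.63), cholesterol synthesis (-1.57), fatty acid and triglyceride synthesis (-0.88), plasma proteins and hepatocyte transcription factors (-1.72), xenobiotic metabolism (-1.67) and ribosome biogenesis (-0.23). They were positive for sinusoidal endothelial (1.60), Kupffer cell (1.27), monocyte (0.99), stellate cell (0.87), T and NK cell (2.00), B cell (2.67), erythroid (4.66) and neutrophil (1.63) markers, immediate early genes (0.84), NF-kB and TNF targets (1.08) and antigen presentation (1.16). Without anti-Gr1 POD1 replicate 3 the medians of Fatty acid and triglyceride synthesis, Cholesterol synthesis and Monocyte and recruited macrophage markers were -0.18, -0.99 and 0.69, the last with its call lost. Antigen presentation lost its call at 0.93 without anti-Gr1 POD2 replicate 3, and without anti-Gr1 POD1 replicate 2 NF-kB and TNF targets stood at 1.80. The median of the Erythroid markers was 2.82 without isotype POD1 replicate 2. Ribosome biogenesis lost its call without isotype POD1 replicate 3 (-0.18), isotype POD2 replicate 3 (-0.15), anti-Gr1 POD1 replicate 2 (-0.18) or anti-Gr1 POD2 replicate 3 (-0.19). Without anti-Gr1 POD1 replicate 3 the medians of plasma proteins and of xenobiotic metabolism turned direction (0.15 and 0.92), as they did with the cross-day pair out (0.05 and 0.72) and with both changes (0.05 and 0.73). Secreted plasma proteins and hepatocyte transcription factors also lost their call without isotype POD1 replicate 2 (-1.56) or anti-Gr1 POD2 replicate 2 (-1.70), and Xenobiotic metabolism without isotype POD1 replicate 2 (-1.57).

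Among single genes, large positive differences were those of Slc4a1 at 6.52, Hbb-bt 4.74, Hbb-bs 4.66, Hba-a2 4.30, Hba-a1 4.25, Ighd 3.84, Cd79a 3.84, Fcmr 3.70 and Pou2af1 3.51, genes of red cells and B cells whose calls were all lost with the pairs merged. The largest negative ones were Rdh16f2 at -5.08, Cdc20 -4.93, Arhgef39 -4.65, Iqgap3 -4.57, Cdca3 -4.49, Cdca2 -4.38, Cenpm -4.15, Ccnb1 -4.14, Nipal1 -4.12 and Ckap2 -4.11. Of the genes named in advance, Foxm1 stood at -3.35, Cdk1 -3.51, Mki67 -3.53, Ccna2 -2.71, Pcna -1.08, Ly6c2 1.44 and Ly6c1 1.47. With both changes Cdc20, Cdca3, Cdca2, Cenpm, Ckap2, Ccnb1, Iqgap3, Cdk1 and Foxm1 still passed, and Rdh16f2, Arhgef39, Nipal1, Mki67, Ccna2, Pcna, Ly6c2 and Ly6c1 did not.

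Chance could not be excluded for this count by splits of the antibody labels within days, of which 100 were drawn. With the real split included, 7 called as many genes as the real 2539, and the highest other called 5692. All 7 were among the 11 that keep the 3 isotype POD2 libraries together, and no split that parted the POD2 groups called a gene, so these counts point to a structure of the samples, the antibody difference at POD2. For the other comparisons 10 splits of 6 libraries are too few to judge chance. At POD1 the real count was 525 and the highest other 296, with 1 split as high, and at POD2 they were 6404 and 0, with 1. For POD2 against POD1 they were 7094 and 0 in isotype, with 1 split as high, and 0 and 29 in the libraries labelled anti-Gr1, with 10.

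Granulocyte transcripts were higher in the libraries labelled anti-Gr1, against the label. A lower share of hepatocyte or acinar RNA, which raises markers of every other cell alike, is excluded as the whole cause, since the granulocyte score minus the Kupffer cell score was 2.85 log2 units higher at POD1 and 2.91 at POD2, with ranges of -4.75 to -4.24 in isotype against -1.88 to -1.33 at POD1, and -5.04 to -4.46 against -1.83 to -1.73 at POD2. Exchanged antibody labels cannot be told apart from a real rise. Mature neutrophil genes were also higher, by a median of 1.07 at POD1 and 2.82 at POD2, but less than early granule genes, at 3.47 and 4.92. Both lists were chosen knowing these libraries, and the difference between them was not tested. A return of immature granulocytes after depletion may account for the same values and was not tested, as the data hold no cell counts.

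Mitotic genes were lower in the libraries labelled anti-Gr1 at POD2. A smaller share of hepatocyte RNA is excluded as the whole cause only if the plasma protein score gauges that share, which was not tested. The mitotic score fell beyond the plasma protein score by 1.60 log2 units (-1.60, with -3.88 to -3.59 in isotype and -5.42 to -5.19 in the libraries labelled anti-Gr1). Each of these ranges includes a near-identical pair. Acinar RNA is excluded as the whole cause, as the median with the acinar score as a covariate was -2.88 and 34 of the 35 genes still passed. Counting the near-identical pairs within groups as separate animals is excluded as the whole cause of these calls. With those pairs merged the median was -2.73 and 34 of the 35 genes still passed. The cross-day pair still counts on both days in that setting. With both changes the median was -3.04, but the anti-Gr1 POD2 group then holds no replicates, so its spread cannot be judged. A lower rate of cell division in these mice was not tested, as no table counts cells or divisions, and stays open, as do exchanged labels or a delay of the whole response.

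The near-identical libraries may be 1 library or 1 RNA pool deposited under 2 names, or separate animals. Their coefficient of variation beyond counting noise was 2.5% in isotype POD2, 6.27% in anti-Gr1 POD2 and 5.02% in the cross-day pair. The 10 other pairs of the same group lay between 21% and 50.2%. The pairs were found by the same counts, so these values are no separate test. Immunoglobulin V genes, which differ between animals with their B cell clones, did not decide, as the highest chi-square per gene within the 3 pairs was 1.16 (1.164) and the lowest among the 63 other pairs 1.11, with a median of 2.36 and 86 genes measured. Scores of other tissues, which may have been carried over at dissection, do not decide either. The largest difference of any of 5 tissue scores was 0.21 log2 units within the pairs and at least 1.84 in the others, but 52 of the 64 genes scored are among those by which the pairs were found. If the cross-day pair is 1 library, either anti-Gr1 POD1 replicate 3 or anti-Gr1 POD2 replicate 3 carries the wrong day. The coefficient of variation beyond counting noise (edgeR) of anti-Gr1 POD1 replicate 3 was 23.3% and 22.9% against anti-Gr1 POD2 replicates 1 and 2, and 44.0% and 50.2% against anti-Gr1 POD1 replicates 1 and 2, so this pair lies nearer to POD2. As the last 2 differ from each other by 42.5%, its day stays open.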

How the results depend on the processing

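All tests with pairs merged, the cross-day pair out, both changes or the acinar score were chosen after the result was seen. The cause was not tested for any value below. Merging and leaving out libraries leave fewer samples, yet several counts rose when libraries were left out. Counts of changed genes stayed within 1.5 times of their value in 87 cases and moved beyond in 33. Of called lists, 1600 values kept direction and call, 202 lost it (104 of them with an estimated correlation) and 8 reversed. Of named genes, 18915 were the same, 1173 lost the call, 670 gained it and 7 reversed. A gene called in neither fit counts as the same here, whatever its direction, so the tally does not measure stable directions. Cyp7a1 at POD1, at 1.77 and at -3.80 with the cross-day pair out, is such a gene. DESeq2 left named genes without an adjusted p, and these give no verdict. Depth limits genes of few counts. The fit of 2 groups alone was not run for the interaction. Correlations of deviations between same-numbered libraries lay between -0.26 and 0.358, and 5 of 12 libraries correlated best with their own number. The near-identical replicates 3 of anti-Gr1 POD1 and POD2 gave only 0.237. A low correlation can therefore not show that replicate numbers do not pair the samples.

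For anti-Gr1 against isotype at POD1 (525 genes) the count was 311 without scaling factors, 1280 with DESeq2, 52 with the 2 groups alone, 298 with the replicate block, 138 with glmTreat, 115 with pairs merged, 2301 with the cross-day pair out, 793 with both, and 124 to 2407 leaving out 1 library. At POD2 (6404) it was 3289 with glmTreat, 3960 merged and 1650 with both. For the interaction (2539) it was 900 with glmTreat, 877 merged, 76 with both, and 1420 to 4187 leaving out 1 library. POD2 against POD1 gave 4143 with glmTreat in isotype (7094), and 91 with DESeq2, 2564 with the cross-day pair out, 545 with both, and 0 to 2900 leaving out 1 library in the libraries labelled anti-Gr1 (0). The replicate block moved no other count by 1.5 times.

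Reversed were, in the interaction, Secreted plasma proteins and hepatocyte transcription factors (0.05 with the cross-day pair out, 0.05 with both, -2.20 to 0.15 leaving out 1 library) and Xenobiotic metabolism (0.72, 0.73 and -2.21 to 0.92). At POD1, Xenobiotic metabolism ranged from -2.24 to 0.89 and Alb from -2.31 to 0.83 leaving out 1 library, Alb was -2.31 with the cross-day pair out and -2.31 with both, and Egfr was -1.13 with the cross-day pair out. Leaving out 1 library moved NF-kB and TNF targets from -0.78 to 0.05 in the libraries labelled anti-Gr1. Without scaling factors Dnajc3, Nat10 and Noc4l stood at -0.10, -0.14 and -0.19 in isotype.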

Other observations

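The tests on the 7 added lists, on genes outside the naming rule and on shared calls without the cross-day pair were all chosen after the results were seen; the overlap of calls between the days was planned.

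RNA of tissues that border the liver or the pancreas varied between libraries. Adrenal steroid genes had a mean log2 CPM of 5.55 and 5.61 in replicates 1 and 2 of anti-Gr1 POD2, which are near-identical, against -0.80 in replicate 3 and at most 2.66 in the other 9 libraries. Their median log2 fold change was 5.75 from POD1 to POD2 in the libraries labelled anti-Gr1, with 0 of 9 passing (9 adjusted over the list alone, camera adjusted p = 6.93e-07, adjusted p = 0.267 with an estimated correlation). For the antibody the median was -1.81 at POD1, with 0 of 9 passing (camera adjusted p = 0.18), and 2.67 at POD2, with 2 rising (0 adjusted over the list alone, camera adjusted p = 0.555). Cyp11b2, aldosterone synthase, had 2 counts over the anti-Gr1 POD1 libraries and 301 over anti-Gr1 POD2. Acinar genes had medians of 1.06 at POD1 and -1.30 at POD2 for the antibody (camera adjusted p = 0.116 and 0.555, 0 of 20 passing on either day), islet genes 1.30 and 1.26 (0.237 and 0.794), adipocyte genes -1.36 and 0.70 (0.0273 and 0.794) and skeletal muscle genes -1.06 and -0.66 (0.0104 and 0.555). With an estimated correlation the adjusted p of the adipocyte and muscle lists at POD1 was 0.679 and 0.698.

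Granule genes of early and of mature granulocytes were separate lists. Early granule genes rose in 11 of 11 for the antibody at POD1 (median log2 fold change 3.47, camera adjusted p = 1.56e-39, adjusted p = 0.00228 with an estimated correlation) and in 10 of 11 at POD2, with 1 falling (median 4.92, camera adjusted p = 1.31e-12, adjusted p = 0.0412 with an estimated correlation). Mature neutrophil genes rose in 4 of 12 at POD1 (5 adjusted over the list alone, median 1.07, camera adjusted p = 1.53e-08, adjusted p = 0.269 with an estimated correlation) and in 10 of 12 at POD2 (median 2.82, camera adjusted p = 1.85e-11, adjusted p = 0.123 with an estimated correlation). Of the 11 early granule and 12 mature neutrophil genes, 9 and 10 are also in the list of neutrophil and granulocytic myeloid markers or another list. Both were chosen knowing these libraries, so their counts are not independent evidence of a direction. Of the granule enzymes of early granulocytes, Mpo (myeloperoxidase) rose by 3.44 at POD1 and 4.92 at POD2 (adjusted p = 0.0114 and 0.000304). Elane (neutrophil elastase) rose by 3.10 and 2.88 (adjusted p = 0.0136 and 0.00279). Prtn3 rose by 2.35 at POD1 (adjusted p = 0.00825) and fell by 1.53 at POD2 (adjusted p = 0.00476), and between the days it rose by 2.88 in the isotype libraries (adjusted p = 0.000181). The interaction of Prtn3 was -3.87 ± 0.49 (SE, adjusted p = 0.000977).

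With the cross-day pair out, the calls of the 2 antibody comparisons overlapped more than independent lists would. They shared 649 higher genes against 182 by chance, and 745 lower genes against 285 by chance, among 15679 tested.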
